A study of Mus musculus with 10 samples.

How the data were processed

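RNA from T cells sorted from mouse spleen was measured by RNA sequencing in 10 libraries, 2 in each of 5 groups. Of the groups, 4 came from T follicular helper (Tfh) cells, which help B cells make antibody in germinal centres, and 1 came from naive CD4 T cells, which have not met antigen. The lupus Tfh cells and the naive cells came from B6.Sle1.Yaa mice, a strain that develops a lupus-like disease. Its Sle1 interval lies on chromosome 1 and its Yaa segment is a piece of the X chromosome duplicated on the Y chromosome. Tfh cells were taken at 2, 4 and 7 months of age and naive cells at 2 months. The remaining Tfh group came from C57BL6 mice on day 8 of infection with LCMV (lymphocytic choriomeningitis virus). Per the labels, Tfh cells were sorted as CD4+ CD44+ GITR− PSGL-1 low, CXCR5 high and PD-1 high cells. The labels give replicate numbers without saying that replicates came from separate animals. The p-values therefore measure the spread between these samples, which may be technical.

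Per the labels, libraries were paired-end and strand-specific and were made from total RNA. The submitters' processing notes name bcl2fastq 2.20.0.422, FastQC 0.11.8, cutadapt 2.5, STAR, SAMtools 1.9, Picard 2.21.1, featureCounts 1.6.4, StringTie 2.0, edgeR 3.26.5, DESeq2 1.22.1 and the GRCm38 build, without the role or order of each. The annotation release is not given in the sources used here. The authors deposited 4 tables, 1 for each Tfh group beside the 2 naive libraries. Each holds 46078 genes, of which 863 had no symbol, and 327 symbols were shared by several identifiers. The expression values the authors deposited are a normalized signal, gene read counts divided by 1 size factor per library that was set within the 4 libraries of a table. The deposited tables also give the authors' log2 fold change of Tfh over naive cells with its standard error. Their p-values and adjusted p-values stand beside it as the authors deposited them, with NA where none was given. The columns of the 7-month libraries carry a name with 8 months, while the labels of the samples give 7, and the age of the labels was used. Coordinates are those of GENCODE mouse release 21 on GRCm38, in which 45229 of the identifiers were found.

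Because each value is a whole number of reads divided by 1 factor, the reads were recovered from the step between low values. All values (100%) came out whole within 0.001 of a read, and the reads of the naive libraries were the same in the 4 tables, with 0 genes differing. The recovered reads of the 10 libraries were then normalized together with trimmed means of M-values (TMM) in edgeR 4.0.16. Levels are given as normalized read counts, the reads divided by the effective library size and multiplied by its mean. The test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(normalized count + 1), with 1 coefficient per group over all 10 libraries and 5 residual degrees of freedom. It was two-sided, with Benjamini-Hochberg adjustment over the 15497 genes with a mean of at least 10 in at least 1 group and a threshold of 0.05. Every adjusted p is from limma unless another tool is named. Fold changes lie on the log2(count + 1) scale, which understates the change of low genes. Against a group with no read, the fold is a lower bound set with a floor of 3 counts over the group. With 1 to 3 reads in a group, the ratio of the groups' levels per read is given with its counting interval. These intervals, at the 95% level, and the Wilson intervals of shares cover counting error only.

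Each Tfh group was compared with the naive cells, the ages with each other, and the mean of the lupus groups with the LCMV group. Comparisons, tests, thresholds and the rule for naming genes were fixed before the data were examined, and so were 25 gene lists. The lists cover the gate, the Tfh programme, naive and quiescent cells, the cell cycle, type I interferon, Th1 and cytotoxic genes, Th2 and Th17 genes, regulatory T cells, inhibitory receptors, T cell receptor induced genes, immediate early genes, senescence-associated genes, chemokine receptors, glycolysis, oxidative phosphorylation, sterol and fatty acid synthesis, the unfolded protein response, the Yaa segment, the Sle1 interval and mitochondrially encoded genes. They also cover markers of B cells, plasma cells, myeloid cells, CD8 T and NK cells, and erythroid cells with platelets. Each list with at least 5 tested members was tested with camera at its preset correlation of 0.01, adjusted over all 200 tests of a list in a comparison. Camera was repeated with an estimated correlation, and none of the 90 calls held there. The rotation test fry, which asks whether the genes of a list move on balance in 1 direction, gave 44 of these 90 calls. Camera sets a list against the other genes and fry does not.

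The rule named, per comparison, the 6 largest and 6 smallest fold changes past the threshold without overlap between the groups' libraries and with a mean of at least 200 in the higher group. It also named the gate genes, up to 4 members of each list by p, and Xist with 4 Y-linked genes. Of the list members it named, the text prints a part that was picked after the values were seen. Bcl6 and Igfbp4 are discussed at 2 months, and Bcl6 in the LCMV group, as members that did not pass. Some of the genes the rule named are not reported here.

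Alternatives fixed in advance were edgeR's quasi-likelihood test and DESeq2 1.42.0 on the recovered reads, DESeq2's size factors, no filter, a minimum mean of 50, pseudocounts of 0.5 and 8, and an absolute log2 fold change of at least 1. The remaining ones were a replicate block, each library left out in turn, a fit of only the libraries compared, and the authors' deposited results. Chosen after seeing the data were array weights, a loess correction (span 0.3) per library for GC content and length, known for 15426 of the tested genes, and 2 sets of libraries left out. One set was the library labelled LCMV replicate 2, left out of the fit shared by the other groups. The other set was 2-month replicate 1, 4-month replicate 1 and LCMV replicate 2, called the 3 doubted libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.

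The recovery of reads was tested on 20 simulated columns of 40000 genes and gave 0 genes with wrong reads. The gene tests were tested on 5 simulated comparisons of the 2-month and naive groups over 15497 genes, with 200 genes changed in each. Limma found 2.39% of the genes changed 2-fold, 48.1% of those changed 4-fold and 90% of those changed 16-fold, with 22 false calls over the 5 simulations. EdgeR found 1.79%, 46.6% and 88.5%, with 17 false calls. DESeq2 found 14.6%, 79.7% and 97.9%, with 325 false calls. Camera found a list of 20 genes raised 4-fold in 5 of 5 simulations and an unchanged list in 0 of 5. Genes were drawn independently of each other in these simulations, so they do not test the preset correlation of camera.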

Results

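Gene expression was measured in splenic Tfh cells of lupus-prone B6.Sle1.Yaa mice at 2, 4 and 7 months of age, in Tfh cells of C57BL6 mice on day 8 of LCMV infection, and in naive CD4 T cells of 2-month B6.Sle1.Yaa mice, with 2 libraries per group. Reads assigned to genes numbered 19435066 and 18294530 in the naive libraries. They numbered 19533879 and 16958682 at 2 months, 19824767 and 18776535 at 4 months, 13820378 and 18073262 at 7 months, and 26912464 and 25592805 in the LCMV group. Mitochondrial reads made up 1.89% to 5.42% of a library. In the replicate pairs, the chi-square per degree of freedom over genes was 16.03 at 7 months, 66.6 in naive cells, 92.86 at 2 months, 133 at 4 months and 319 in the LCMV group. Each pair thus differed by far more than sampling noise.

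The gate of the sort was read first, as a check of the labels. Cd44, the activation marker (chromosome 2, 102811141-102901665, GRCm38), lay at 135 ± 28.3 normalized counts (SD, n = 2) in naive cells and at 5335 to 11292 in the 8 Tfh libraries. Pdcd1, which encodes PD-1 (chromosome 1, 94038305-94052553), lay at 171 and 182 in naive cells and at 1908 to 17341 in Tfh cells. Tnfrsf18, which encodes GITR, was higher in Tfh cells although the labels call them GITR-negative. Its RNA lay at 540 and 513 in naive cells and at 825 to 2225 in Tfh cells, and surface protein was not measured. Cxcr5, the receptor that guides cells into the B cell follicle (chromosome 9, 44511787-44561877), lay at 274 and 300 in naive cells, at 2976 to 10992 in the lupus Tfh libraries and at 9758 in LCMV replicate 1. In the library labelled LCMV replicate 2 it lay at 138, below both naive libraries, and Selplg, which encodes PSGL-1 and is low in the gate, lay there at 28848 against 10897 in replicate 1. Among the lupus libraries, 2-month replicate 1 kept 7090 counts of Igfbp4, a gene abundant in naive cells, and 9122 of Satb1, against 20.6 and 228 in replicate 2. Xist, the RNA of the inactive X chromosome (chromosome X, 103460366-103483254), lay at 4947 and 12799 in the LCMV libraries and at 0 to 14.9 in the others. The Y-linked gene Ddx3y lay at 0 and 35.6 in the LCMV libraries and at 471 to 5603 in the others. Sex, strain and infection thus changed together between the LCMV group and all others.

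**Figure D1:**
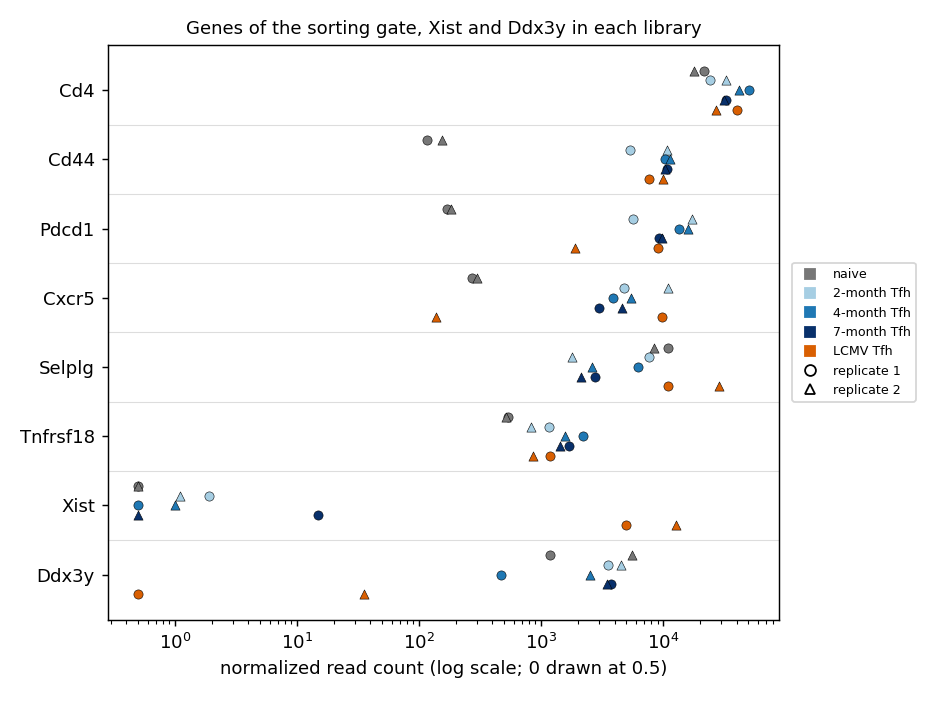
Normalized read counts (log axis, 0 drawn at 0.5) of the 6 genes of the sorting gate, of Xist and of Ddx3y, with 1 point per library, coloured by group and shaped by replicate. Cxcr5 lay at 138 in the library labelled LCMV replicate 2 and at 2976 or more in the other 7 Tfh libraries, and Xist lay at 4947 and 12799 in the LCMV group and at no more than 14.9 elsewhere.

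The first comparison asked how Tfh cells of young lupus-prone mice differed from naive CD4 T cells of the same age. At 2 months Tfh cells carried far more Il21, the cytokine by which Tfh cells drive germinal centre B cells (chromosome 3, 37222759-37232636), with 5478 ± 4120 normalized counts against 13.8 ± 13.9 (SD, n = 2 each). That was a log2 fold change of 8.71 ± 1.36 (SE), adjusted p = 0.0099. Ifng, the Th1 cytokine, rose from 5.09 ± 2.65 to 1495 ± 697 counts (log2 7.93 ± 0.79). Lratd1 rose (log2 8.39, adjusted p = 0.0163), as did Ascl2, a transcription factor that promotes the Tfh fate (8.28 ± 1.70). The extracellular matrix genes Npnt and Tnc rose too, at 597 times (counting interval 165 to 4930) and 452 times (155 to 2190) the naive level. The largest falls were those of Lbp (−5.49 ± 1.18), the motor protein Myo10 (−2.86 ± 0.68), Mical3 (−2.73 ± 0.60), the quiescence factor Bach2 (−2.53 ± 0.58), the insulin receptor substrate Irs2 (−2.35 ± 0.57) and Nckap5l (−2.19 ± 0.50). In all, 1098 genes rose and 114 fell, a split that was 1551 and 511 with DESeq2.

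Of the gate genes, Cd44 rose by 5.81 ± 0.33 (SE) and Pdcd1 by 5.81 ± 0.71 on the log2 scale, with adjusted p of 0.000949 and 0.0046. Tnfrsf18, which encodes GITR, did not pass (0.89 ± 0.27, adjusted p = 0.0911), nor did Selplg (−1.37 ± 0.74, 0.329), Cd4 (0.50 ± 0.30, 0.376) or Cxcr5 (4.66 ± 1.59, 0.131). Cxcr5 passed with adjusted p = 0.00146 once the library labelled LCMV replicate 2 was left out of the shared spread. The gate list lay higher (adjusted p = 0.00749, and adjusted p = 0.435 with an estimated correlation), with 4 members past the threshold adjusted over the list alone. Tfh cells were sorted on the proteins of these genes, so gate list calls against naive cells check the sort and are no finding. The list also holds Selplg and Tnfrsf18, whose proteins were selected as low and negative.

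Of the 20 genes of the Tfh programme, 10 rose and 0 fell, and 18 rose adjusted over the list alone. Examples were the transcription factor Maf (5.25 ± 0.44 SE), the signalling regulator Rgs16 (6.04 ± 0.57), Angptl2 (7.44 ± 1.07) and S1pr2, a receptor that holds cells in germinal centres (3.52 ± 0.46). The list lay higher than other genes (adjusted p = 1.14e-09, and adjusted p = 0.446 with an estimated correlation). Bcl6, the master regulator of Tfh cells, did not pass (2.71 ± 0.95, adjusted p = 0.14, and 0.0155 with LCMV replicate 2 out of the shared spread). Of 18 naive and quiescence genes, 2 fell, Bach2 and the transcription factor Lef1 (−1.86 ± 0.45), and the same number fell adjusted over the list alone. The list lay lower (adjusted p = 3.25e-08, and adjusted p = 0.446 with an estimated correlation). Igfbp4 (−5.91 ± 2.25, adjusted p = 0.172) did not pass, and reached −10.08 with adjusted p = 0.0047 without 2-month replicate 1.

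Cell cycle genes lay higher (adjusted p = 2.06e-08, and adjusted p = 0.518 with an estimated correlation): 12 of 20 rose, 16 adjusted over the list alone, among them the spindle factor Tpx2 (4.54 ± 0.75 SE) and cyclin B1, Ccnb1 (3.64 ± 0.59). Of 16 Th1 and cytotoxic genes, 5 rose and 9 did so adjusted over the list alone, including the chemokine receptor Cxcr3 (7.10 ± 0.59), the Th1 regulator Tbx21 (5.17 ± 0.57) and the granzyme Gzmk (6.51 ± 0.75). That list lay higher with adjusted p = 2.87e-05, and adjusted p = 0.518 with an estimated correlation. Inhibitory receptors lay higher (adjusted p = 0.000222, and adjusted p = 0.435 with an estimated correlation), with 6 of 14 risen, 8 risen and 1 fallen adjusted over the list alone. Examples were Tigit (5.84 ± 0.49), Lag3 (5.47 ± 0.73) and Ctla4 (4.13 ± 0.40). Senescence-associated genes lay higher (adjusted p = 1.01e-05, and adjusted p = 0.435 with an estimated correlation), with 6 of 10 risen, 8 adjusted over the list alone. They included Spp1, which encodes osteopontin (7.38 ± 0.74; chromosome 5, 104435118-104441050), and the cell cycle inhibitor Cdkn2c (3.93 ± 0.55).

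Smaller groups also moved at 2 months. Glycolysis genes lay higher (adjusted p = 0.002, and adjusted p = 0.538 with an estimated correlation), with 1 of 16 risen and 7 adjusted over the list alone. Chemokine receptors lay higher (adjusted p = 0.0215, and adjusted p = 0.435 with an estimated correlation), with 4 of 18 risen, 6 risen and 1 fallen adjusted over the list alone, but not without the 3 doubted libraries (adjusted p = 0.0578). The interferon list lay lower (adjusted p = 0.0264, and adjusted p = 0.692 with an estimated correlation), although its only call, the antiviral GTPase gene Mx1, rose (1.65 ± 0.35 SE, adjusted p = 0.0307). Among other named genes, the early gene Jun fell (−2.05 ± 0.29) and the activation-induced factor Irf4 (2.04 ± 0.27), the interferon-inducible Ifi204 of the Sle1 interval (6.03 ± 0.97), the anti-inflammatory cytokine Il10 (5.14 ± 0.80) and Gpm6b of the distal X chromosome (7.14 ± 1.23) rose. Markers of other cell types were measured beside these. The B cell factor Pax5 rose to 322 times the naive level (counting interval 89.2 to 2660).

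Single libraries weighed on this comparison. The number of genes called was 195 without naive replicate 1, 313 without naive replicate 2, 214 without 2-month replicate 2 and 1454 without 2-month replicate 1. Of the 36 called genes named here, 14 passed without naive replicate 1 (adjusted p of the others 0.0518 to 0.274), 21 without naive replicate 2 (0.0514 to 0.191), 13 without 2-month replicate 2 (0.0602 to 0.272) and all but Tnc and Mx1 without 2-month replicate 1 (0.0562 and 0.0578). EdgeR's quasi-likelihood test did not call Tnc, Lbp, Myo10, Mical3, Bach2, Irs2, Nckap5l and Lef1 (adjusted p 0.0523 to 0.0806). Myo10, Bach2, Irs2, Nckap5l and Lef1 did not pass without a filter (0.0543 to 0.0651), nor did Lef1 with a pseudocount of 8 (0.0509) or Myo10 and Irs2 after the GC and length correction (0.0563 and 0.0569). Npnt, Ifng, Cd44, Pdcd1, Maf, Rgs16, S1pr2, Cxcr3, Tbx21, Gzmk, Tigit, Ctla4 and Spp1 passed in every alternative run.

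**Figure D2:**
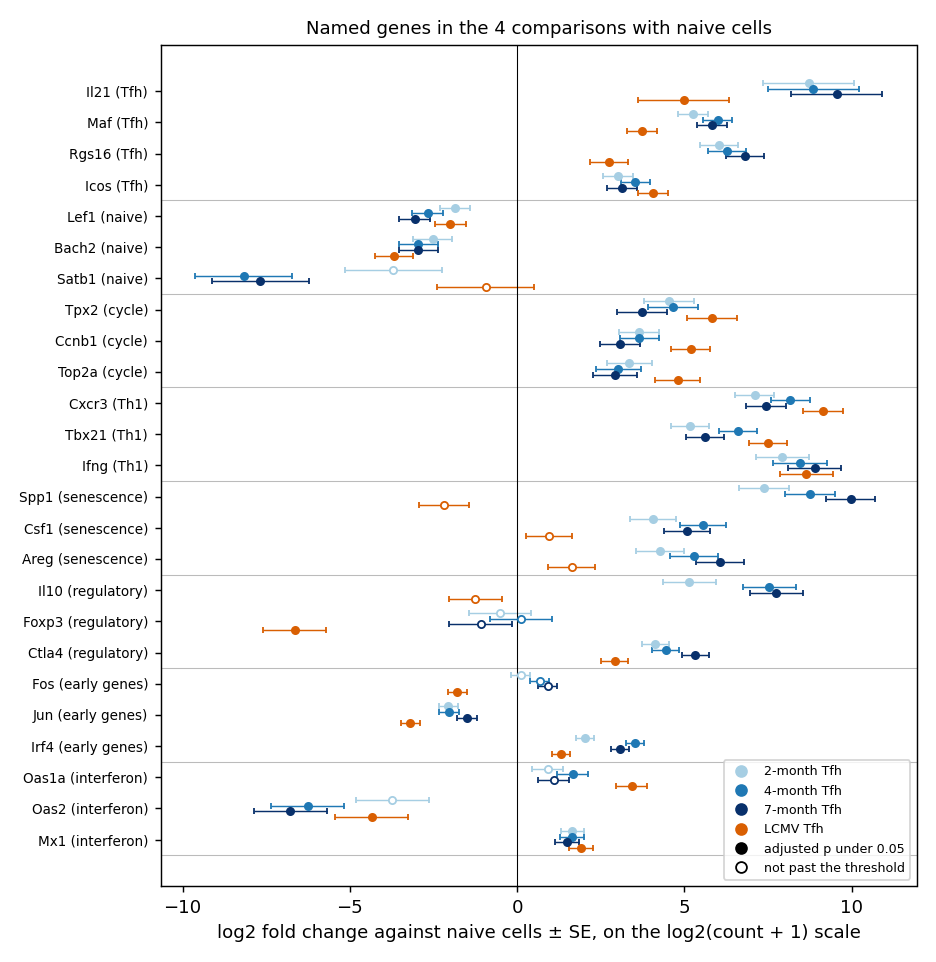
Log2 fold changes against naive cells, with bars of 1 SE, of named genes from the fixed lists in the 2-, 4- and 7-month and LCMV Tfh groups, filled where adjusted p was under 0.05. Values lie on the log2(count + 1) scale, so those of genes with almost no reads in 1 group are no measure of the fold; Il21, Maf, Cxcr3 and Ifng were past the threshold in all 4 groups.

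At 4 months Sostdc1, a secreted antagonist of BMP and Wnt signals that marks a subset of Tfh cells (chromosome 12, 36314139-36318452), lay at 17920 ± 2170 normalized counts against 19.0 ± 15.6 in naive cells (SD, n = 2 each). Its log2 fold change was 10.07 ± 2.65 (SE), adjusted p = 0.0401. The calcium exchanger gene Slc24a3 had no read in naive cells and was at least 428-fold higher. Il21 rose by 8.86 ± 1.36, Lratd1 by 8.87 (adjusted p = 0.00793) and Spp1 by 8.76 ± 0.74 on the log2 scale, and Npnt lay at 699 times the naive level (counting interval 194 to 5770). The largest falls were those of Igfbp4, a binder of insulin-like growth factors (chromosome 11, 99041244-99054392), which went from 23490 ± 1570 to 31.8 ± 18.8 counts, and of the chromatin organizer Satb1, from 18970 ± 3250 to 68.7 ± 34.8. With 1 to 3 reads in the 4-month libraries, the naive levels of Sorcs2, Pdlim4, Lypd6b and the AMP deaminase gene Ampd1 were 1430 (counting interval 257 to 56600), 1340 (240 to 52800), 861 (155 to 34000) and 475 times (131 to 3920) the Tfh levels. In all, 1848 genes rose and 515 fell. The split was 2069 and 1163 with DESeq2 and 1957 and 945 after the GC and length correction.

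The gate list lay higher at 4 months (adjusted p = 0.00316, and adjusted p = 0.435 with an estimated correlation), with 4 of 6 members risen and 5 adjusted over the list alone. Cd44 rose by 6.32 ± 0.33 (SE), Pdcd1 by 6.38 ± 0.71, Tnfrsf18 by 1.82 ± 0.27 (adjusted p = 0.00457) and Cd4 rose 2.33-fold (adjusted p = 0.0302, and 0.0561 with DESeq2's size factors). Cxcr5 (4.00 ± 1.59, adjusted p = 0.137, and 0.00126 with LCMV replicate 2 out of the shared spread) and Selplg (−1.24 ± 0.74, adjusted p = 0.3) did not pass. Of the 20 Tfh genes, 13 rose, 17 adjusted over the list alone, including Maf (5.99 ± 0.44), Rgs16 (6.29 ± 0.57) and the costimulator Icos (3.54 ± 0.45). The list lay higher with adjusted p = 2.11e-08, and adjusted p = 0.448 with an estimated correlation. Of 18 naive and quiescence genes, 12 fell, the same number as adjusted over the list alone. They included the kinase Txk (−4.11 ± 0.68), Lef1 (−2.68 ± 0.45) and the cytoskeletal gene Actn1 (−4.97 ± 0.87), and the list lay lower (adjusted p = 1.5e-08, and adjusted p = 0.446 with an estimated correlation).

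Effector genes moved in the same comparison. Th1 and cytotoxic genes lay higher (adjusted p = 5.5e-05, and adjusted p = 0.518 with an estimated correlation). Of the 16, 8 rose, 10 risen and 1 fallen adjusted over the list alone, with Cxcr3 at 8.17 ± 0.59 (SE), Tbx21 at 6.60 ± 0.57 and Ifng at 8.46 ± 0.79. Cell cycle genes lay higher (adjusted p = 1.2e-06, and adjusted p = 0.528 with an estimated correlation), with 12 of 20 risen, 16 adjusted over the list alone, such as Tpx2 (4.65 ± 0.75) and cyclin A2, Ccna2 (4.79 ± 0.79). Inhibitory receptors lay higher (adjusted p = 0.000754, and adjusted p = 0.435 with an estimated correlation), with 6 of 14 risen, 8 risen and 1 fallen adjusted over the list alone, such as Tigit (6.89 ± 0.49), Lag3 (6.89 ± 0.73) and Ctla4 (4.45 ± 0.40). Senescence-associated genes lay higher (adjusted p = 4.52e-06, and adjusted p = 0.435 with an estimated correlation), with 7 of 10 risen, 9 adjusted over the list alone. Cdkn2b, a cell cycle inhibitor with no naive read, was at least 87.9-fold higher, and Csf1, a growth factor of macrophages, rose by 5.57 ± 0.69.

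Of 16 glycolysis genes, 6 rose, 12 adjusted over the list alone, such as the lactate exporter Slc16a3 (3.50 ± 0.63 SE) and hexokinase 2, Hk2 (2.94 ± 0.61). As a list they lay higher with adjusted p = 0.00029, and adjusted p = 0.518 with an estimated correlation. Regulatory T cell genes lay higher (adjusted p = 0.0362, and adjusted p = 0.435 with an estimated correlation), with 5 of 11 risen, 5 adjusted over the list alone, Il10 among them (7.53 ± 0.80; chromosome 1, 131019845-131024974). Without the 3 doubted libraries the adjusted p of that list was 0.0698. Among its members without a rise, Foxp3 lay at 525 and 543 counts against 468 and 519 in naive cells. Il2ra lay at 313 and 322 against 344 and 374, and Lrrc32 at 23.0 and 26.7 against 58.7 and 59.0. The sterol list lay lower (adjusted p = 0.028, and adjusted p = 0.533 with an estimated correlation) with 1 of 16 members risen and 1 fallen. The interferon list lay lower (adjusted p = 0.0384, 0.0535 with DESeq2's size factors, and adjusted p = 0.714 with an estimated correlation) with 2 of 21 members risen, Mx1 (1.64 ± 0.35) among them, and 2 fallen, including Oas2 (−6.26 ± 1.10). Irf4 rose (3.52 ± 0.27) and the growth regulator Myc fell (−2.48 ± 0.57).

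Red cell transcripts moved with these groups. Of 9 erythroid and platelet markers, 8 rose, all 9 adjusted over the list alone, such as the globins Hbb-bs (3.81 ± 0.67 SE) and Hba-a1 (3.92 ± 0.67). Together these markers lay higher with adjusted p = 1.55e-05, and adjusted p = 0.446 with an estimated correlation. The number of genes called was 746 without naive replicate 1, 782 without naive replicate 2, 986 without 4-month replicate 1 and 1737 without 4-month replicate 2. Of the 41 called genes named here, 22 passed without naive replicate 1 (adjusted p of the others 0.0537 to 0.179), 25 without naive replicate 2 (0.0523 to 0.188), 30 without 4-month replicate 1 (0.0507 to 0.199) and 33 without 4-month replicate 2 (0.0517 to 0.109). Sostdc1 did not pass without any 1 of these libraries (0.0988 to 0.179). Without a filter Sostdc1 and Pdlim4 did not pass (0.0561 and 0.0573), nor did Pdlim4 with a pseudocount of 0.5 (0.0509), Mx1 in a fit of only the libraries compared (0.062), or Mx1 and Cd4 without the 3 doubted libraries (0.0717 and 0.078). Slc24a3, Il21, Spp1, Npnt, Cd44, Tnfrsf18, Pdcd1, Maf, Rgs16, Icos, Cxcr3, Tbx21, Ifng, Tigit, Lag3, Ctla4, Cdkn2b, Csf1, Irf4 and Il10 passed in every alternative run.

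At 7 months Spp1 reached 6208 ± 843 normalized counts against 5.17 ± 0.273 in naive cells (SD, n = 2 each), a log2 fold change of 9.97 ± 0.74 (SE), adjusted p = 0.000531. Il21 stood at 8301 ± 698 counts (log2 9.55 ± 1.36) and Sostdc1 rose by 10.08 ± 2.65. Slc24a3 was at least 419-fold higher, while Tnc lay at 1270 times the naive level (counting interval 434 to 6150). The largest falls were those of Igfbp4 (−8.52 ± 2.25), Satb1 (−7.68 ± 1.45), the neuropeptide receptor Vipr1 (−7.51 ± 1.27) and Sorcs2 (−7.84 ± 1.64). The naive level of Pdlim4 was 1140 times (counting interval 205 to 45000) and that of Lypd6b 367 times (102 to 3030) the 7-month level. In all, 2001 genes rose and 719 fell, against 3891 and 2477 with array weights, 3170 and 2330 in a fit of only the libraries compared, 2122 and 1249 after the GC and length correction, and 656 and 62 without 7-month replicate 1.

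The gate list lay higher at 7 months (adjusted p = 0.0166, and adjusted p = 0.435 with an estimated correlation), with 3 of 6 members risen and 5 risen and 1 fallen adjusted over the list alone. Cd44 (6.29 ± 0.33 SE), Pdcd1 (5.74 ± 0.71) and Tnfrsf18 (1.56 ± 0.27, adjusted p = 0.00775) rose. Cd4 (0.70 ± 0.30, adjusted p = 0.15), Selplg (−1.98 ± 0.74, 0.108) and Cxcr5 (3.69 ± 1.59, 0.157, and 0.00172 with LCMV replicate 2 out of the shared spread) did not pass. Of the 20 Tfh genes, 13 rose, 19 adjusted over the list alone, such as Maf (5.82 ± 0.44), Rgs16 (6.81 ± 0.57) and Angptl2 (8.17 ± 1.07). The list lay higher with adjusted p = 2.29e-08, and adjusted p = 0.448 with an estimated correlation. Of 18 naive and quiescence genes, 11 fell, 13 adjusted over the list alone, such as Lef1 (−3.06 ± 0.45) and Satb1, and the list lay lower (adjusted p = 2.06e-08, and adjusted p = 0.446 with an estimated correlation).

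Cell cycle genes lay higher at 7 months (adjusted p = 0.000484, and adjusted p = 0.593 with an estimated correlation), with 9 of 20 risen, 13 adjusted over the list alone, such as Tpx2 (3.75 ± 0.75 SE) and Ccnb1 (3.07 ± 0.59). Th1 and cytotoxic genes lay higher (adjusted p = 0.000322, and adjusted p = 0.533 with an estimated correlation), with 7 of 16 risen, 10 risen and 1 fallen adjusted over the list alone, such as Cxcr3 (7.44 ± 0.59) and Ifng (8.90 ± 0.79). Inhibitory receptors lay higher (adjusted p = 0.00082, and adjusted p = 0.435 with an estimated correlation), with 6 of 14 risen, 8 adjusted over the list alone. Tigit rose by 6.50 ± 0.49, Lag3 by 6.54 ± 0.73 and Ctla4 by 5.32 ± 0.40. Senescence-associated genes lay higher (adjusted p = 1.29e-05, and adjusted p = 0.435 with an estimated correlation), with 7 of 10 risen, 9 adjusted over the list alone. Cdkn2b was at least 77-fold higher, and the growth factor Areg lay at 115 times the naive level (counting interval 31.8 to 948).

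At 7 months the sterol and fatty acid list lay lower (adjusted p = 0.000754, and adjusted p = 0.446 with an estimated correlation), with 4 of 16 fallen and 1 risen, 6 fallen adjusted over the list alone. Falls were seen for the squalene epoxidase Sqle (−1.91 ± 0.49 SE) and Srebf2, the regulator of cholesterol synthesis (−1.02 ± 0.26). The interferon list lay lower (adjusted p = 0.0018, and adjusted p = 0.6 with an estimated correlation), with 3 of 21 fallen and 1 risen. Its falls were those of Oas2 (−6.78 ± 1.10), Usp18 (−2.08 ± 0.59, adjusted p = 0.0472, but 0.0538 with edgeR, 0.0629 without a filter and 0.0518 with a minimum mean of 50) and the nucleic acid sensor Zbp1 (−1.18 ± 0.27). Among early and receptor-induced genes the heat shock gene Hspa1a fell (−5.39 ± 1.26), while the phosphatase Dusp1 (2.00 ± 0.45), the NF-kB brake Tnfaip3 (1.58 ± 0.41) and Irf4 (3.08 ± 0.27) rose. Il10 rose by 7.74 ± 0.80.

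Markers of other cells rose at the same age. All 9 erythroid and platelet markers rose, such as Hba-a1 (5.35 ± 0.67 SE) and the red cell anion exchanger Slc4a1 (5.19 ± 0.52), and the list lay higher (adjusted p = 7.38e-07, and adjusted p = 0.435 with an estimated correlation). Of 12 myeloid markers 6 rose, 8 adjusted over the list alone, among them the neutrophil genes S100a8 (5.12 ± 1.44) and S100a9 (5.71 ± 1.44), with S100a9 at 442 and 2301 counts in the 7-month libraries. S100a8 did not pass without a filter (adjusted p = 0.0614), with a minimum mean of 50 (0.0512) or with a pseudocount of 0.5 (0.0654). That list lay higher with adjusted p = 0.00488, and adjusted p = 0.563 with an estimated correlation. Of 13 B cell markers 5 rose, 8 adjusted over the list alone, such as the MHC class II chain Cd74 (1.43 ± 0.33) and Ighd (4.57 ± 1.05), and Pax5 lay at 182 times the naive level (counting interval 50.4 to 1500). That list lay higher with adjusted p = 0.00495, and adjusted p = 0.435 with an estimated correlation. The antibody gene Ighg2b rose (4.09 ± 1.08), the only call among 9 plasma cell markers, whose list did not pass (adjusted p = 0.225).

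Every library of this comparison weighed on its count of calls, which was 840 without naive replicate 1, 961 without naive replicate 2, 718 without 7-month replicate 1 and 803 without 7-month replicate 2. Of the 45 called genes named here, 22 passed without naive replicate 1 (adjusted p of the others 0.0523 to 0.222), 24 without naive replicate 2 (0.055 to 0.191), 20 without 7-month replicate 1 (0.0525 to 0.19) and 23 without 7-month replicate 2 (0.0502 to 0.258). Pdlim4 did not pass without a filter (0.0502). Spp1, Il21, Slc24a3, Cd44, Pdcd1, Maf, Rgs16, Angptl2, Lef1, Cxcr3, Ifng, Tigit, Lag3, Ctla4, Cdkn2b, Areg, Irf4, Slc4a1, Hba-a1 and Il10 passed in every alternative run.

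**Figure D3:**
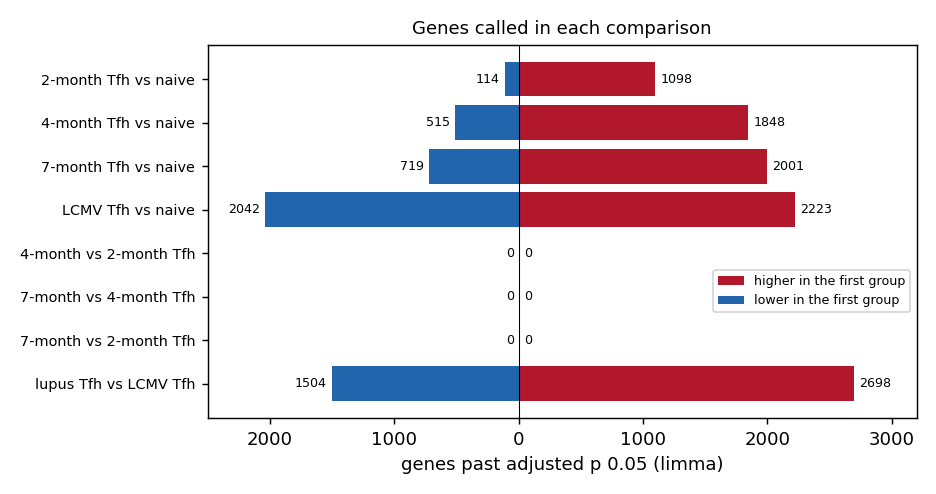
Number of genes past an adjusted p of 0.05 (limma) in each comparison, with genes higher in the first group to the right and genes lower to the left. The comparisons with naive cells ran from 1098 higher and 114 lower at 2 months to 2223 higher and 2042 lower in the LCMV group, and the comparisons between ages had 0.

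The 3 lupus ages shared 986 genes higher and 81 lower than in naive cells, such as Il21, Spp1, Maf and Il10, where independent lists of these sizes would share 16.9 and 0.176. With the LCMV group added, 571 genes were higher in all 4 Tfh groups, such as Cxcr3, Tbx21, Ifng, Icos and Cd44, and 70 were lower, such as Bach2 and Lef1. Independent lists would share 2.43 and 0.0232. In 20 simulations with all groups unchanged and common simulated naive libraries, 0 genes were shared in either direction. Unchanged groups give few calls, so this 0 does not measure what the shared controls add. All 4 comparisons used the same naive libraries, which cannot be split with at least 2 in each part, so part of the excess may come from the shared controls.

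The LCMV comparison set Tfh cells of an acute viral infection against the naive cells of the lupus-prone strain, so that sex and strain differed too. Cxcr3 rose to 13670 ± 3170 normalized counts from 28.5 ± 24.9 (SD, n = 2 each), a log2 fold change of 9.15 ± 0.59 (SE), adjusted p = 0.000181. The calcium-binding genes S100a6 (8.99 ± 0.42) and S100a4 (8.75 ± 0.55) and the membrane gene Emp1 (8.94 ± 0.74) rose, and Esm1 lay at 1380 times the naive level (counting interval 248 to 54700). Igfbp4 fell from 23490 ± 1570 counts (SD, n = 2) to 2.5 and 21.5 in the LCMV libraries. The sialyltransferase St8sia6 (2716 ± 720 to 6.27 ± 0.508 counts) and the TGF-beta family receptor Acvrl1 (−8.22 ± 1.71) fell too. Xist was at least 5730-fold higher, and the Y-linked Ddx3y (−8.74 ± 1.56), Kdm5d (−8.34 ± 1.21) and Eif2s3y (−8.17 ± 1.15) fell. In all, 2223 genes rose and 2042 fell. After the correction for GC content and length the split was 3106 higher of 4966.

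Of the gate genes, Cd44 (6.02 ± 0.33 SE), Pdcd1 (4.55 ± 0.71) and Tnfrsf18 (0.93 ± 0.27, adjusted p = 0.0361) rose. Cd4 (0.74 ± 0.30, adjusted p = 0.101), Selplg (0.89 ± 0.74, 0.401) and Cxcr5 (2.02 ± 1.59, 0.379) did not pass. Without the library labelled LCMV replicate 2 Cxcr5 changed by 5.08 with adjusted p = 0.00135, and without replicate 1 by −1.05. The gate list lay higher with adjusted p = 0.00734, and adjusted p = 0.435 with an estimated correlation, with 3 members past the threshold adjusted over the list alone. Of 20 Tfh genes, 9 rose, the same number as adjusted over the list alone, such as Icos (4.07 ± 0.45), Maf (3.74 ± 0.44) and Sh2d1a, the adaptor SAP of contacts between T and B cells (1.88 ± 0.27). The list lay higher with adjusted p = 0.000502, and adjusted p = 0.542 with an estimated correlation. Bcl6 did not pass (−0.23 ± 0.95, adjusted p = 0.885), with 2026 counts in replicate 1 and 207 in the library labelled LCMV replicate 2, and changed by 1.41 without the latter. Naive and quiescence genes lay lower (adjusted p = 6.65e-05, and adjusted p = 0.518 with an estimated correlation), with 10 of 18 fallen, 11 adjusted over the list alone, such as Igfbp4 and Bach2 (−3.68 ± 0.58).

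Of 20 cell cycle genes, 17 rose, 19 adjusted over the list alone, such as Tpx2 (5.82 ± 0.75 SE), Ccnb1 (5.19 ± 0.59) and the topoisomerase Top2a (4.80 ± 0.66). The libraries stood apart here, with Mki67 at 1285 counts in replicate 1 and 13658 in the library labelled replicate 2. Taken as a list these genes lay higher with adjusted p = 5.71e-09, and adjusted p = 0.509 with an estimated correlation. Th1 and cytotoxic genes lay higher (adjusted p = 2.54e-05, and adjusted p = 0.518 with an estimated correlation), with 9 of 16 risen and 1 fallen, 9 risen and 1 fallen adjusted over the list alone, such as Tbx21 (7.49 ± 0.57) and Ifng (8.64 ± 0.79). Of that list Gzmb lay at 13.5 counts in replicate 1 and at 23877 in the library labelled replicate 2. Glycolysis genes lay higher (adjusted p = 1.52e-05, and adjusted p = 0.5 with an estimated correlation), with 13 of 16 risen, 14 adjusted over the list alone, such as Hk2 (4.41 ± 0.61) and Gapdh (2.40 ± 0.41). Genes of oxidative phosphorylation lay higher (adjusted p = 0.000426, and adjusted p = 0.545 with an estimated correlation), with 6 of 18 risen, 11 adjusted over the list alone, such as the complex I subunit Ndufb8 (1.31 ± 0.21). Of 13 immediate early genes 5 fell and 1 rose, with Jun at −3.19 ± 0.29 and Fos at −1.78 ± 0.28 (list lower, adjusted p = 0.00972, and adjusted p = 0.446 with an estimated correlation).

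Other groups differed in their members. Il1rl1, the IL-33 receptor (chromosome 1, 40429570-40465415), rose by 8.16 ± 0.91 (SE) as the only call among 5 tested Th2 and Th17 genes, whose list did not pass (adjusted p = 0.181). Foxp3, the regulatory T cell factor (chromosome X, 7573644-7595245), fell from 493 ± 36.3 to 4.20 ± 2.42 counts (SD, n = 2 each) and the regulatory T cell gene Gpr83 fell by 6.83 ± 1.41 on the log2 scale. That list had 4 of 11 members fallen and 1 risen and did not pass (adjusted p = 0.651). The antiviral gene Oas1a rose (3.43 ± 0.46) among 4 risen and 1 fallen of 21 interferon genes, with no call of the list (adjusted p = 0.19). Sdf2l1 rose (2.44 ± 0.26) among 5 risen and 1 fallen of 12 unfolded protein response genes (adjusted p = 0.0505). Genes of the Sle1 interval lay higher (adjusted p = 0.00978, and adjusted p = 0.435 with an estimated correlation), with 5 of 15 risen, 5 adjusted over the list alone. Chemokine receptors also lay higher (adjusted p = 0.0362, and adjusted p = 0.435 with an estimated correlation), with 5 of 18 risen, but not after the GC and length correction (adjusted p = 0.11) or without the 3 doubted libraries (0.0775).

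Markers of CD8 T and NK cells lay higher beside these groups (adjusted p = 0.0183, and adjusted p = 0.518 with an estimated correlation), with 3 of 7 risen. Gzma rose by 6.08 ± 0.84 (SE) with 322 and 1802 counts, and the NK receptor Klrc1 by 7.99 ± 1.30 with 176 and 3734, the higher values in the library labelled LCMV replicate 2. The list did not pass without the 3 doubted libraries (adjusted p = 0.131) or after the GC and length correction (0.0518). Hbb-bs was 57.3 times higher in naive cells (counting interval 15.9 to 473). The number of genes called was 1672 without naive replicate 1, 1319 without naive replicate 2, 4326 without LCMV replicate 1 and 4902 without LCMV replicate 2. Of the 37 called genes named here, all but Igfbp4, Acvrl1, Tnfrsf18 and Gpr83 passed without naive replicate 1 (adjusted p of these 0.0554 to 0.12), 31 passed without naive replicate 2 (0.0548 to 0.158), all but Tnfrsf18 without LCMV replicate 1 (0.128) and all without LCMV replicate 2. Tnfrsf18 also did not pass without a filter (0.0547), with array weights (0.0891) or in the authors' values (0.079), where Gpr83 did not either (0.102), and a fit of only the libraries compared did not call Tnfrsf18, Gpr83 and Ndufb8 (0.0563 to 0.107).

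The ages were compared with each other to ask whether lupus Tfh cells change as disease advances. Red cell transcripts lay higher at each later age: Hbb-bs lay at 64 and 74 normalized counts at 2 months, 1030 and 456 at 4 months and 2740 and 946 at 7 months, and Slc4a1 at 12 and 17, 75 and 51, and 374 and 270. No single gene passed, with 0 calls by limma and by edgeR in each of the 3 comparisons. Limma gave 938 genes with an unadjusted p under 0.05 from 2 to 4 months, 1203 from 4 to 7 months and 1157 from 2 to 7 months, and DESeq2 called 93, 16 and 165. From 2 to 7 months the smallest adjusted p was 0.215. The limma values were 4.52 ± 0.67 (SE) for Hbb-bs and 4.36 ± 0.52 for Slc4a1 (both adjusted p = 0.215), 5.32 ± 1.44 for S100a9 (0.394), 4.85 ± 1.08 for Ighg2b (0.306), 1.05 ± 0.27 for Irf4 (0.373), 2.59 ± 0.74 for Spp1 (0.42), 2.66 ± 0.75 for Cdkn2b (0.415) and 2.60 ± 0.80 for Il10 (0.472). From 2 to 4 months Irf4 differed by 1.48 ± 0.27 and Hbb-bs by 3.29 ± 0.67 (both adjusted p = 0.701), and from 4 to 7 months Hspa1a differed by −4.83 ± 1.26 (0.553).

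Several lists stood apart from other genes between ages. Erythroid markers lay higher at 4 than at 2 months (adjusted p = 5.05e-10, and adjusted p = 0.435 with an estimated correlation), at 7 than at 4 months (0.000502, and adjusted p = 0.505 with an estimated correlation) and at 7 than at 2 months (1.23e-16, and adjusted p = 0.435 with an estimated correlation), with 8, 2 and 9 of 9 past the threshold adjusted over the list alone. From 2 to 7 months lists lay lower for oxidative phosphorylation (adjusted p = 1.55e-05), sterol synthesis (4.09e-05) and the cell cycle (0.000502), and higher for myeloid (0.000147) and B cell markers (0.00315), with adjusted p of 0.518, 0.435, 0.593, 0.518 and 0.435 with an estimated correlation. From 4 to 7 months glycolysis lay lower (adjusted p = 1.71e-05, and adjusted p = 0.5 with an estimated correlation). Mitochondrially encoded genes lay higher (adjusted p = 0.00158, and adjusted p = 0.518 with an estimated correlation) but not after the GC and length correction (0.808, in the other direction). The naive list lay lower at 4 and at 7 than at 2 months (adjusted p = 0.000842 and 0.00084, both with adjusted p = 0.542 with an estimated correlation), which ended without the 3 doubted libraries (0.166 and 0.839). Senescence-associated genes lay higher at 4 than at 2 months (adjusted p = 0.00461, and adjusted p = 0.435 with an estimated correlation).

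No gate gene passed between ages, though the gate list lay higher at 4 than at 2 months (adjusted p = 0.0362, and adjusted p = 0.438 with an estimated correlation, and adjusted p = 0.425 without the 3 doubted libraries). From 2 to 4 months the log2 differences were 0.72 ± 0.30 (SE) for Cd4, 0.51 ± 0.33 for Cd44, 0.93 ± 0.27 for Tnfrsf18 (each adjusted p = 0.701), 0.13 ± 0.74 for Selplg (0.975), −0.66 ± 1.59 for Cxcr5 (0.926) and 0.57 ± 0.71 for Pdcd1 (0.834). From 4 to 7 months they were −0.52 ± 0.30 for Cd4 (0.554), −0.03 ± 0.33 for Cd44 (0.978), −0.26 ± 0.27 for Tnfrsf18 (0.691), −0.73 ± 0.74 for Selplg (0.685), −0.31 ± 1.59 for Cxcr5 (0.95) and −0.64 ± 0.71 for Pdcd1 (0.717). From 2 to 7 months they were 0.20 ± 0.30 for Cd4 (0.962), 0.48 ± 0.33 for Cd44 (0.817), 0.67 ± 0.27 for Tnfrsf18 (0.628), −0.61 ± 0.74 for Selplg (0.939), −0.97 ± 1.59 for Cxcr5 (0.972) and −0.07 ± 0.71 for Pdcd1 (adjusted p = 1).

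Lupus Tfh cells, as the mean of the 3 ages, were then set against LCMV Tfh cells, to ask how Tfh cells of autoimmunity and of infection differ. Il10 lay at 861 ± 565 normalized counts in lupus (SD, n = 6) and at 2.49 ± 3.51 in LCMV Tfh cells (SD, n = 2), a log2 difference of 8.06 ± 0.65 (SE), adjusted p = 0.000312. Spp1 lay at 8290 times (counting interval 1490 to 327000) and the imprinted RNA Rian at 1720 times (308 to 67800) the LCMV level. The matrix gene Fbn2, with no read in the LCMV libraries, was at least 672-fold higher, and the integrin Itgb8, an activator of TGF-beta, differed by 9.85 ± 0.98. In the other direction Il1rl1 (−5.87 ± 0.75), Rbm47 (−5.29 ± 0.49), Igf2bp3 (−5.28 ± 0.74) and Cd163l1 (−5.81 ± 1.42, adjusted p = 0.0211) were lower in lupus. So were the ribosomal RNA gene n-R5-8s1 (−7.02 ± 0.62; chromosome 18, 73533403-73533550) and Xist (−11.68 ± 0.97), and the Y-linked Ddx3y (8.69 ± 1.27) and Eif2s3y (8.67 ± 0.94) were higher. In all, 2698 genes were higher and 1504 lower in lupus Tfh cells, which changed to 2345 and 1935 with DESeq2's size factors and to 2228 and 2990 after the GC and length correction.

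The gate list did not pass (adjusted p = 0.885). Selplg was lower in lupus (−2.42 ± 0.60 SE, adjusted p = 0.0223). Cd4 (0.07 ± 0.24, adjusted p = 0.854), Cd44 (0.12 ± 0.27, 0.764), Tnfrsf18 (0.49 ± 0.22, 0.133), Cxcr5 (2.09 ± 1.30, 0.262) and Pdcd1 (1.43 ± 0.58, 0.103) did not pass. Of 20 Tfh genes, 10 were higher in lupus, 12 higher and 1 lower adjusted over the list alone, such as Rgs16 (3.64 ± 0.46), Maf (1.95 ± 0.36) and Ascl2 (6.74 ± 1.39). That list lay higher with adjusted p = 0.0357, and adjusted p = 0.673 with an estimated correlation. The LCMV libraries stood apart in it, by a median log2 of −2.40 in the library labelled replicate 2 against replicate 1. Regulatory T cell genes lay higher (adjusted p = 0.000813, and adjusted p = 0.435 with an estimated correlation), with 7 of 11 higher, 8 adjusted over the list alone. They included Foxp3 (6.16 ± 0.76), Il10, the actin-capping gene Capg (3.74-fold, adjusted p = 0.00303) and Ctla4 (1.71 ± 0.33). Of these, Foxp3 reached 1102 counts in 2-month replicate 1 and 109 to 543 in the other lupus libraries. Senescence-associated genes lay higher (adjusted p = 0.0044, and adjusted p = 0.435 with an estimated correlation), with 6 of 10 higher, 7 adjusted over the list alone, such as Csf1 (3.96 ± 0.56) and Areg (3.58 ± 0.58).

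Part of the early and receptor-induced genes were higher in lupus Tfh cells. Of 13 immediate early genes 6 were higher, 6 adjusted over the list alone, such as Fos (2.35 ± 0.23 SE), Dusp1 (2.26 ± 0.37) and Jun (1.33 ± 0.24), with adjusted p = 0.0166 for the list, and adjusted p = 0.464 with an estimated correlation. Of 12 receptor-induced genes 5 were higher, 5 adjusted over the list alone, such as Irf4 (1.57 ± 0.22), with adjusted p = 0.0357, and adjusted p = 0.435 with an estimated correlation. Inhibitory receptors lay higher (4 of 14 higher, adjusted p = 0.0391, and adjusted p = 0.518 with an estimated correlation). Genes of the Yaa segment lay higher (4 of 15, 5 adjusted over the list alone, adjusted p = 0.0183, and adjusted p = 0.496 with an estimated correlation), with Gpm6b at 7.11 ± 1.00 (chromosome X, 166238911-166388988). Gpm6b also rose against naive cells of the same strain at 2 months. The list did not pass in LCMV Tfh against these naive cells (camera adjusted p = 0.232). Tlr7, on the same part of the X chromosome, lay at 332 and 25.7 counts in the LCMV libraries and at 123 to 409 in lupus. Genes of the Sle1 interval lay lower (5 of 15 lower, adjusted p = 0.0215, 0.0691 without the 3 doubted libraries, 0.0747 after the GC and length correction, and adjusted p = 0.435 with an estimated correlation), with the signalling receptor Cd48 at −1.67 ± 0.37.

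Part of the interferon, energy and sterol genes were lower in lupus Tfh cells. Of 21 interferon genes 5 were lower, 8 adjusted over the list alone, such as Oas1a (−2.21 ± 0.38 SE), Oas3 (−2.15 ± 0.40) and Usp18 (−2.35 ± 0.48), with adjusted p = 1.29e-05 for the list, and adjusted p = 0.528 with an estimated correlation. Of 18 genes of oxidative phosphorylation 9 were lower, 13 adjusted over the list alone, such as Cox5a (−1.09 ± 0.18) and cytochrome c, Cycs (−1.01 ± 0.15), with adjusted p = 3.4e-06, and adjusted p = 0.518 with an estimated correlation. Sterol and fatty acid genes lay lower (7 of 16, 10 adjusted over the list alone, adjusted p = 6.78e-05, and adjusted p = 0.435 with an estimated correlation), such as the squalene synthase Fdft1 (−1.11 ± 0.16). Glycolysis lay lower (6 of 16, 8 adjusted over the list alone, adjusted p = 0.00196, and adjusted p = 0.538 with an estimated correlation), as did the unfolded protein response (3 of 12, adjusted p = 0.0183, and adjusted p = 0.5 with an estimated correlation). The cell cycle list lay lower (2 of 20, adjusted p = 3.48e-05, and adjusted p = 0.542 with an estimated correlation), but not without the 3 doubted libraries (0.339). The Th1 and cytotoxic list lay lower (4 of 16 lower and 1 higher, adjusted p = 0.0174, and adjusted p = 0.642 with an estimated correlation) and turned higher without these libraries (0.791) and did not pass after the GC and length correction (0.139).

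Markers of other cells differed as well. Erythroid markers lay higher in lupus (7 of 9, adjusted p = 3.48e-05, and adjusted p = 0.446 with an estimated correlation), with Hbb-bs at 1060 times the LCMV level (counting interval 293 to 8740). CD8 T and NK cell markers lay lower (4 of 7, adjusted p = 0.00688, and adjusted p = 0.5 with an estimated correlation), such as Gzma (−4.57 ± 0.68 SE), but not without the 3 doubted libraries (0.153). The number of genes called was 2501 without 7-month replicate 1 and 2485 without 7-month replicate 2. Of the 36 called genes named here, Selplg did not pass without 7-month replicate 2 (adjusted p = 0.0549), nor did Cd163l1 without LCMV replicate 1 (0.0913) or either of them without LCMV replicate 2 (0.0608 and 0.131). With array weights Cd163l1, Selplg, Ctla4, Jun and Cox5a did not pass (0.0574 to 0.195).

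Reads of marker genes of other cell types were summed in each library and scaled by its reads on all genes (RPM). Erythroid and platelet markers took 4.17 and 4.81 RPM in naive cells, 7.94 and 9.20 at 2 months, 105 and 46.2 at 4 months, 278 and 112 at 7 months, and 0.706 and 2.74 in the LCMV group. B cell markers took 541 and 444 in naive cells, 954 and 1575 at 2 months, 966 and 1344 at 4 months, 1360 and 1857 at 7 months and 1176 and 567 in the LCMV group. Myeloid markers took 43.6 and 37.5 in naive cells, 77.5 and 61.5 at 2 months, 143 and 69.6 at 4 months, 159 and 416 at 7 months and 59.6 and 783 in the LCMV group, where the library labelled replicate 2 had the higher value. CD8 T and NK cell markers took 86.9 and 344 in the LCMV libraries, 17.9 and 14.2 in naive cells, 58.5 and 23.1 at 2 months and 11.4 to 19.8 at the later ages. Regulatory T cell genes took 174 and 220 in naive cells, 1079 to 2111 in the lupus libraries and 406 and 348 in the LCMV group. Plasma cell markers ran from 65.5 to 316.

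**Figure D4:**
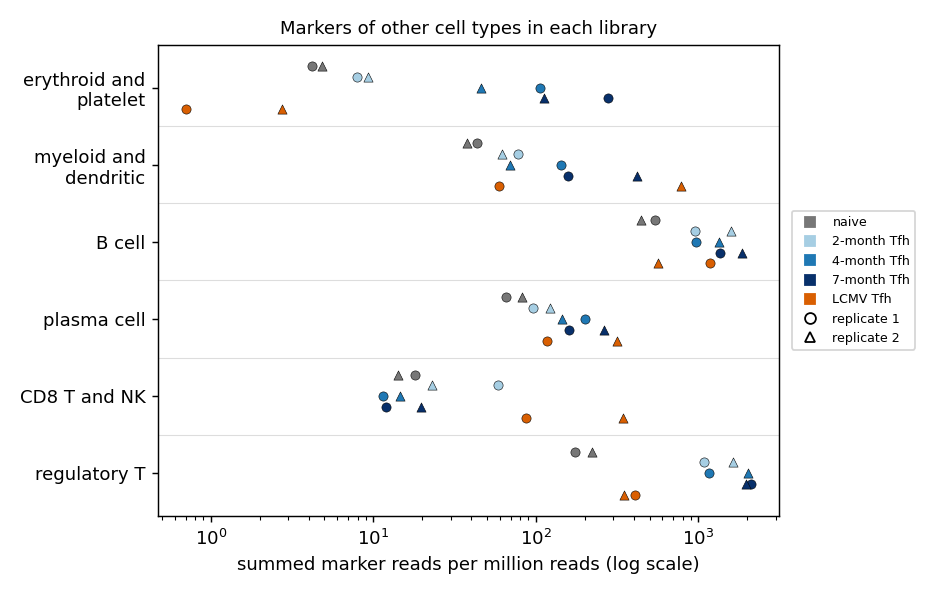
Summed marker genes of other cell types in RPM (log axis), with 1 point per library, coloured by group and shaped by replicate. Erythroid and platelet markers ran from 0.706 in LCMV replicate 1 to 278 in 7-month replicate 1, and myeloid markers reached 783 in the library labelled LCMV replicate 2.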

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

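The tests of the 3 patterns weighed here were chosen after their results were seen, except the 2 on GC content and transcript length, whose predictions were written before. A tested difference between 2 groups marked the results that follow. In 4202 genes the change from naive cells differed between the lupus Tfh cells, as the mean of the 3 ages, and the LCMV Tfh cells. Of these, 58 were higher than in naive cells in at least 1 lupus comparison and lower in the LCMV group, and 10 were the reverse. The 58 included the red cell transcripts Hbb-bs, Hba-a1, Slc4a1 and Hbb-bt. Nrn1, a cell surface gene first known from neurons (chromosome 13, 36725361-36735131), stood 3.20, 6.06 and 5.81 above naive cells on the log2 scale at 2, 4 and 7 months and fell by 2.89 in the LCMV group, a difference of 7.91 ± 0.34 (SE), adjusted p = 3.02e-05. The membrane protease gene Mmp14 rose by 2.37, 2.41 and 2.38 and fell by 2.74, a difference of 5.12 ± 0.45. In the other direction, the difference of the pyrimidine salvage gene Uck2 was −2.07 ± 0.17.

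Named genes were marked by the same test. The log2 difference between lupus and LCMV Tfh cells was 8.06 for Il10, 6.16 for Foxp3, 2.35 for Fos and 1.57 for Irf4, and it was −5.87 for Il1rl1, −2.21 for Oas1a and −1.09 for Cox5a. Sex, strain, infection and the T cell receptor V genes weighed below differ between these groups, so none of them can be named as the source. Technical differences between the libraries cannot be set apart from these either and were not tested. The ribosomal RNA gene n-R5-8s1 had 751 and 289 reads in the LCMV libraries against 1 to 5 elsewhere. The mitochondrial gene mt-Nd3 had 0 and 1 reads there against 38 to 71. No outlier rule was applied because every group had 2 libraries.

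The library labelled LCMV replicate 2 had little Cxcr5 (138 normalized counts) and Bcl6 (207), with Icos (12639) and Maf (7125) above naive cells, and carried many Th1 and cytotoxic transcripts. Against replicate 1, the Tfh list lay at a median log2 difference of −2.40, and the Th1 and cytotoxic list lay 5.66 above the Tfh list. CD8 T or NK cells were excluded as the main content, because Cd8a, Cd8b1, Ncr1 and Klrb1c together made 2.70% of the Cd4 level, and a trend with GC content and length was excluded because 103% of the gap between the 2 lists was left after its correction. CD4 T cells outside the Tfh gate or another wrongly labelled sample cannot be told apart from a difference between the infected animals. Cxcr5 (0.482 of the naive mean) is part of the pattern. Pdcd1 lay at 10.8 times the naive mean, but its 1908 counts were the lowest of all Tfh libraries. No activated CD4 T cells from outside the gate were sequenced beside it, so Pdcd1 decides neither way. The difference between the animals was not tested. Nor were myeloid cells, which the CD4 gate of the labels would remove. Itgam lay at 6733 and Itgax at 7944 counts, against 0.8 and 1.7 in replicate 1, with the myeloid gene Lyz2 at 359.

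Of the lupus libraries, 2-month replicate 1 kept transcripts of naive cells. In 13 genes chosen as abundant in naive cells and low in the other 5 lupus libraries, its median level was 0.398 of the naive mean. Naive cells alone were excluded, because 3 regulatory T cell genes lay at least 1.5-fold above all other lupus and naive libraries, and a GC and length trend was excluded with 108% of the share left. Foxp3 (1102 against 543 counts), Il2ra (1262 against 381) and Lrrc32 (313 against 59.0) lay at least 2.03 times above the highest other library, but the other 8 genes of that list lay at 0.117 to 0.864 of it (median of all 11, 0.487). CD4 T cells of more than 1 kind, regulatory T cells among them, thus cannot be told apart from a less advanced Tfh state at 2 months. That state was not tested. The GITR-negative gate of the labels would remove regulatory T cells. Tnfrsf18, which encodes GITR, nevertheless lay at 1159 counts in this library, against 540 and 513 in naive cells.

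Nearly all T cell receptor reads on V genes in both LCMV libraries came from 1 V gene per chain. Trbv13-1 (chromosome 6, 41116007-41116468) took 98.6% (Wilson interval 98.6 to 98.7) and 99.1% (99.0 to 99.1) of the Trbv reads, and Trav14d-3-dv8 (chromosome 14, 53078452-53079045) took 97.1% (97.0 to 97.3) and 97.0% (96.8 to 97.2) of the Trav reads. Clones with different V genes in each library were excluded by the same Trbv gene at 98.6% or more in both, and reads shared between near-identical segments by its share of at most 8.37% in the other 8 libraries. Cells that carry 1 rearranged receptor, as in a receptor-transgenic line, cannot be told apart from several clones that share these V genes, the same or others in each library: Trbj2-5 (chromosome 6, 41543453-41543501) took only 44.4% and 42.1% of Trbj reads and Traj15 18.2% and 15.3% of Traj reads, and J segments had few reads (6351 and 6468 for Trbj). The strain and the infection of these animals stay open as the source and were not tested.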

How the results depend on the processing

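Array weights, the GC and length correction and the 2 sets of left-out libraries were chosen after results were seen. Of 244 results for single named genes, 195 were past the threshold, 114 of these passed in every alternative run, and 24 of the others passed in at least 1. The numbers called were 1212, 2363, 2720 and 4265 at 2, 4 and 7 months and in the LCMV group against naive cells, 0 between ages, and 4202 between lupus and LCMV Tfh cells. DESeq2 gave 2062 at 2 months and 93, 16 and 165 between ages (4 over 2, 7 over 4, 7 over 2 months). Limma with a pseudocount of 8 gave 2 at 7 over 2 months. Array weights came out the same for both libraries of each pair, such as 0.343 in the LCMV group and 3.74 at 7 months. They thus weighted whole groups and could not mark down a single library. With them the numbers were 1932 at 2 months, 6368 at 7 months, 2575 for LCMV and 1280 between lupus and LCMV. Leaving LCMV replicate 2 out of the shared fit gave 2108 and 3582 at 2 and 4 months. Without the 3 doubted libraries the numbers were 3752, 3596, 5182, 6421 and 6444, and 1811 genes rather than 641 were shared by all 4 Tfh groups. A fit of only the libraries compared gave 5500 at 7 months and 1202 for LCMV, and the authors' deposited values gave 1906 at 2 and 4907 at 7 months (4896 of them among the genes tested here). The authors' calls and those made here went 0 times in opposite directions. Leaving out 1 library at a time, where a lone library was assumed to vary like the others, gave 195 to 1454 at 2 months, 746 to 1737 at 4 months, 718 to 961 at 7 months, 1319 to 4902 for LCMV, 0 between ages and 2485 to 4303 between lupus and LCMV. Of 90 list tests past the threshold 0 held with an estimated correlation, and fry passed 53 of all 200, 44 of these 90 among them. With the replicate number as a block the numbers were 1304, 2527, 3075, 4721, 0 for each pair of ages, 4765 and 87 lists. With the block 5 of the 90 lists no longer passed: interferon and chemokine receptors at 4 months (adjusted p = 0.0531 each), CD8 T and NK cells at 4 against 2 months (0.0531), myeloid cells at 7 against 4 months (0.0556) and Tfh in lupus against LCMV (0.0542). Of the called genes named in the text, S100a8 at 7 months did not pass with the block (0.0512). The deviations of same-numbered libraries correlated with −0.18 (7-month and LCMV pairs) to 0.78 (naive and 4-month pairs). The median change of all genes was 0.13 at 2 months and 0.17 between lupus and LCMV, and 0.02 and 0.04 with DESeq2's size factors. In simulations limma found 2.39% of genes changed 2-fold at this number of libraries, and 12657 to 14287 genes per library had 10 reads or more, so small changes and low genes were missed.

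Among single genes, signs turned only for differences that had not passed, and the cause was not tested. Of the 90 lists 3 turned: without the 3 doubted libraries, Th1 and cytotoxic genes lay higher in lupus than in LCMV cells (adjusted p = 0.791) and glycolysis lower at 4 than at 2 months (0.0572), and after the GC and length correction mitochondrially encoded genes lay lower at 7 than at 4 months (0.808). Leaving out 1 library at a time gave ranges that crossed 0. Against naive cells in the LCMV group they were −1.05 to 5.08 for Cxcr5 and −1.87 to 1.41 for Bcl6. From 2 to 4 months they were −0.92 to 1.17 for Selplg and −0.23 to 1.37 for Pdcd1, and from 4 to 7 months −0.064 to 0.033 for Cd44, −0.52 to 0.039 for Tnfrsf18 and −0.63 to 0.002 for Cxcr5. From 2 to 7 months they were −0.020 to 0.41 for Cd4, −0.021 to 0.98 for Cd44, −1.65 to 0.43 for Selplg and −0.87 to 0.74 for Pdcd1. Between lupus and LCMV Tfh cells they were −0.97 to 5.16 for Cxcr5, −0.21 to 0.35 for Cd4 and −0.077 to 0.32 for Cd44. In the LCMV group Bcl6 was −0.23 in limma, 0.55 with edgeR, 0.58 with DESeq2, 1.52 without the 3 doubted libraries and 0.57 in the authors' values. From 2 to 4 months Selplg was −0.085 with edgeR and −0.11 with DESeq2, and Pdcd1 was −0.12 without the 3 doubted libraries. From 4 to 7 months Cd44 was 0.011 with DESeq2 and 0.005 with its size factors, and Tnfrsf18 was 0.039 without the 3 doubted libraries, where Selplg was 0.47 from 2 to 7 months. Between lupus and LCMV Tfh cells Cxcr5 was −0.071 with DESeq2, and without the 3 doubted libraries Cxcr5 was −0.89, Cd4 −0.39 and Tnfrsf18 −0.12. There Cd4 was −0.077 with DESeq2, −0.058 with its size factors and −0.073 after the GC and length correction, and Cd44 was −0.005 with DESeq2's size factors and −0.060 after that correction.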

Other observations

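The gene families named here and their tests were chosen after the results were seen. They were not repeated with the GC and length correction. Over all genes, that correction turned the split between lupus and LCMV Tfh cells from 2698 higher and 1504 lower to 2228 and 2990. Proteasome genes, which degrade proteins and feed antigen presentation, rose in LCMV Tfh cells, with 26 of 37 past the threshold (22 with DESeq2's size factors), such as Psma1 (log2 1.27 ± 0.17 SE) and Psmd14 (1.06 ± 0.16). The family lay higher (adjusted p = 8.41e-10, and adjusted p = 0.685 with an estimated correlation). In lupus against LCMV Tfh cells 29 of them were lower (adjusted p = 6.59e-15, and adjusted p = 0.609 with an estimated correlation), Psma1 by −0.89 and Psmd14 by −1.05. Of 17 tRNA synthetase genes, which load amino acids for translation, 9 were lower in lupus (12 with DESeq2's size factors), such as Gars (−1.38 ± 0.15) and Kars (−1.09 ± 0.16), with adjusted p = 1.7e-05, and adjusted p = 0.615 with an estimated correlation. Of 15 collagen genes 8 were higher in lupus, such as Col5a3 (5.81 ± 0.57), Col16a1 (6.26 ± 0.96) and Col27a1 (4.43 ± 0.44), with adjusted p = 0.000417, and adjusted p = 0.321 with an estimated correlation. Part of this came from falls in the LCMV group, where 6 fell and 0 rose against naive cells (camera adjusted p = 0.0418, and 0.609 with an estimated correlation). At 2, 4 and 7 months 2, 3 and 3 rose and 0, 2 and 2 fell. Col27a1 passed at no lupus age (−1.09, 0.36 and 0.89) and fell in the LCMV group (−4.37).

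S100 calcium-binding genes rose against naive cells in all 4 Tfh groups, with 5, 7, 7 and 7 of 10 past the threshold at 2, 4 and 7 months and in the LCMV group, the neutrophil genes S100a8 and S100a9 among those at 7 months. S100a6 rose by 6.72, 8.06, 7.55 and 8.99 on the log2 scale, and S100a11 by 3.55, 4.10 and 3.75 at the 3 ages. The adjusted p of the family was 4.24e-05, 4.93e-06, 4.93e-06 and 0.000404, and 0.609, 0.584, 0.584 and 0.609 with an estimated correlation. Interleukin genes rose in the lupus groups, 4, 5 and 6 of 9, such as Il15 (3.41, 5.41 and 5.90) and Il18 (4.26, 4.79 and 5.06). That family had adjusted p of 0.000785, 0.000248 and 0.000236, and 0.321 with an estimated correlation each time. In the LCMV group 3 of 9 rose, Il15 (2.60) and Il18 (4.48) among them, and the family did not pass (camera adjusted p = 0.256). Between lupus and LCMV Tfh cells Il15 differed by 2.31 ± 0.57 (limma adjusted p = 0.022) and Il18 by 0.23 ± 0.52 (0.777). The 81 ribosomal protein genes lay lower at each lupus age (median log2 −0.80, −0.96 and −1.30, with 0, 0 and 2 fallen, the last being 7 with DESeq2's size factors). Their adjusted p was 9.03e-13, 1.86e-12 and 1.98e-18, and 0.755, 0.755 and 0.691 with an estimated correlation. At 7 months 5 of 7 chaperonin genes, which fold actin and tubulin, fell, such as Cct5 (−1.12 ± 0.24 SE) and Cct2 (−0.87 ± 0.19), with adjusted p = 0.00185, and adjusted p = 0.615 with an estimated correlation. Semaphorin genes had 6, 8 and 8 of 17 risen at the 3 ages, and the family did not pass (adjusted p 0.056, 0.0862 and 0.122).

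Reads of 2 of the T cell receptor constant genes were higher in the LCMV libraries. Trbc2 had 222964 and 177985 reads there against 9507 to 18849 in the other libraries, and Trac 154721 and 103091 against 15341 to 26555, while Trbc1 had 6490 and 5519 against 5633 to 9667. Deviations between the replicates followed GC content in naive cells (Spearman 0.59) and at 4 months (0.65), and followed length with −0.39 and −0.44. At 2 months the values were 0.17 for GC content and −0.32 for length, in the LCMV group 0.21 and −0.24, and at 7 months 0.06 and 0.02.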
